A study of Xenopus laevis with 4 samples.

How the data were processed

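Small RNA libraries from epidermal explants of Xenopus laevis embryos, a frog used widely in developmental biology, were compared at stage 11.5 (gastrula, non ciliated) and stage 26 (tailbud, ciliated). Each stage was represented by 2 libraries, named a and b, which the series describes as technical replicates of 1 pool of 50 explants. Every p-value below therefore covers the spread between libraries of a stage and not the spread between pools of embryos. Stages were taken from the developmental stage label, because the source name of each library b gives a slightly later stage than that label. Libraries were made with the SREK kit of Ambion, per the labels' protocols. The sequencer, the aligner, the mismatches allowed and the miRNA database release are not given in the sources used here.

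The deposited table lists 98 miRNAs under Xenopus tropicalis names, each with a mature sequence, and 1 column per library. Its values are CPM (reads of a miRNA scaled to a fixed total of miRNA reads) as deposited by the authors: each column sums to 1000000 over the listed miRNAs. Within a column each value was a whole multiple of the smallest nonzero value, within a tolerance of 1e-06, so that this value is worth 1 read. This gave 22668 and 30406 miRNA reads for libraries a and b of stage 11.5, and 46892 and 41878 for libraries a and b of stage 26. These totals cover reads assigned to the listed miRNAs and not the whole libraries. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Genomic positions were not used here.

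A count-based quasi-likelihood test had been planned and was replaced because the deposited values are CPM, and because the recovery of whole reads rests on 98 values per column, with no independent check. Floors, intervals, ratios of pooled reads and TMM factors rest on that recovery. The test used instead was limma (version 3.58.1, R version 4.3.3) with a mean-variance trend on log2(CPM divided by a scaling factor, plus a pseudocount of 50 CPM), with Benjamini-Hochberg adjustment over the tested miRNAs and a threshold of 0.05. Fold changes on this scale understate the change of low miRNAs. A miRNA at 0 in both libraries of a stage gets the same value in both, so its spread in that stage is 0. As planned, scaling factors came from the trimmed mean of M values (TMM), with 30% of M values and 5% of A values trimmed at each end, computed from the recovered reads. As planned, miRNAs were tested if they reached 10 reads at the median depth (276.7 CPM) in at least 2 libraries and 15 reads in total, which left 52. Folds called scaled are TMM scaled, and folds in share compare the deposited CPM. Where a stage was at 0, the fold is a lower bound against a floor of 3 reads over both libraries of that stage, which is 56.5 CPM at stage 11.5 and 33.8 CPM at stage 26. Where a stage had 1 to 3 reads, the ratio of pooled reads is given with its exact 95% interval. Shares of reads have exact (Clopper-Pearson) 95% binomial intervals per library.

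There were 16 miRNA lists fixed before the data were examined, matched by miRNA number, and the 5 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01. Named miRNAs followed a rule also fixed beforehand: the miR-449/34 list, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 100 CPM and 1 direction in all 4 library pairs, the 5 highest miRNAs of each stage, and up to 3 tested members of each other list. This named 31 miRNAs. The fit was tested on 40 simulated tables of this comparison at each of 3 noise levels, with 16 miRNAs changed in each. Noise between libraries had an SD of 0.105, 0.210 or 0.420 on the log2 scale, which is 0.5, 1 and 2 times the median spread between libraries of a stage. The median SE was 0.201, 0.277 and 0.451, against 0.354 in the data, so the data lie between the second and the third level. The fit recovered 81.8%, 68.6% and 24.1% of the 2-fold changes and 97.6%, 97.6% and 77.2% of the 4-fold changes. It called 2.05%, 2.15% and 1.35% of the unchanged miRNAs, with 47.4, 47.05 and 47.9 miRNAs tested on average. Every simulated library started from the mean CPM over both stages, with changes of 2-fold or 4-fold. The simulated tables thus lack a drop of miR-427 as large as in the data. These rates therefore do not cover error from scaling across that drop.

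Alternatives covered other scalings, filters, pseudocounts, each library left out in turn, the replicate letter as a block, rows of a family summed, voom weights on recovered reads, and rows left out. The planned DESeq2 alternative was not run, for the same reason as the planned test. Letters a and b are not stated to pair libraries across stages.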

Results

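The data were miRNA profiles of embryonic frog epidermis before and after the appearance of ciliated cells. Stage 11.5 and stage 26 were each represented by 2 libraries, described as made from 1 pool of 50 explants. Libraries a and b held 22668 and 30406 miRNA reads at stage 11.5, and 46892 and 41878 at stage 26. Of 98 listed miRNAs, 59 were above 0 at stage 11.5 and 92 at stage 26, with 6 seen at stage 11.5 alone and 39 at stage 26 alone. miR-427 held 19731 and 24832 of the reads in libraries a and b of stage 11.5, and 3548 and 2912 in those of stage 26. Far fewer stage 11.5 reads were thus left for other miRNAs, so rows seen at stage 26 alone can reflect depth. Across miRNAs, log2 CPM of libraries a and b correlated with Pearson's r = 0.968 at stage 11.5 and 0.984 at stage 26, and miRNAs are not independent replicates. The 2 libraries of a stage still differed by more than counting noise, with a chi-square per degree of freedom of 20.6 at stage 11.5 and 7.10 at stage 26, most of it in miR-20b, miR-93a, miR-93b and miR-92a. Without these rows the chi-square per degree of freedom was 5.6 and 2.69, still above counting noise. Intervals from counting error are therefore too narrow for the other miRNAs too. Values are means ± SD over the 2 libraries of a stage.

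The comparison asked which miRNAs differ in the epidermis between the non ciliated and the ciliated stage. Ciliation and developmental age differ together between these stages, so their effects cannot be told apart. At stage 11.5 a single miRNA, miR-427, an early embryonic miRNA known for clearing maternal mRNA, made up 84.4% ± 3.80 (SD, n = 2) of miRNA reads. At stage 26 it made up 7.26% ± 0.433 (SD, n = 2), and miR-449, known from multiciliated epithelia, had become the most abundant miRNA with 38.8% ± 0.567 (SD, n = 2). Of 52 tested miRNAs, 20 rose and 11 fell after TMM scaling (limma, adjusted p under 0.05), and 29 of these 31 changed at least 2-fold (18 higher, 11 lower). The scaling moved the stages against each other by 1.98 on the log2 scale (3.95-fold): in the deposited CPM, 37 miRNAs were higher and 6 lower, so 86.0% of calls were higher against 64.5% after scaling. With the miR-427 family left out of the totals, 14 were higher and 14 lower. The 20 that rose after scaling were also higher in CPM. Of the 11 that fell, 6 were also lower in CPM, 4 were not called and miR-1b was higher. With 1 stage 26 library left out, the calls dropped to 11 (without a) and 12 (without b) of 53 and 52 tested. The calls of miR-34b, miR-449, miR-218, miR-30a-5p, miR-130b, let-7b, let-7f, miR-126, miR-363-3p, miR-429, miR-203, miR-1b and miR-23a were then lost under both of these omissions. Their fitted changes kept their direction, with log2 6.25 and 6.16 against 6.26 for miR-34b and 1.24 and 1.18 against 1.22 for miR-449.

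**Figure D1:**
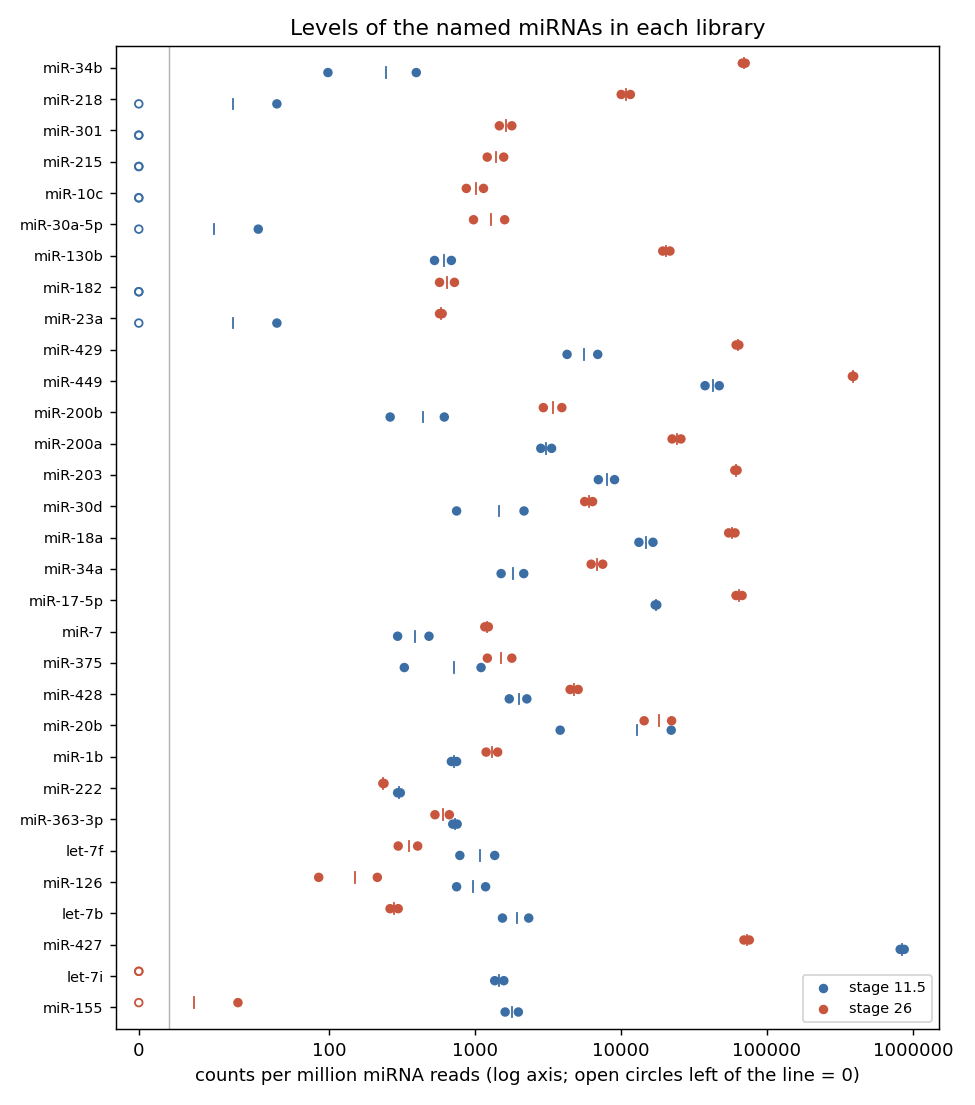
CPM of miRNA reads (horizontal log axis, with 0 drawn as open circles left of the line) of the 31 named miRNAs, ordered by scaled fold change. Points are libraries and ticks the means of the 2 libraries of a stage. miR-449 lay at 37674 and 47129 CPM at stage 11.5 and at 384437 and 392449 CPM at stage 26, and miR-427 went the other way.

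The miR-449/34 list went from 4.45% ± 0.602 to 46.5% ± 0.701 of reads (SD, n = 2), and from 28.8% ± 3.16 to 50.1% ± 0.522 with the miR-427 family left out of the totals. The 95% intervals were 3.77% to 4.29% and 4.63% to 5.12% for libraries a and b of stage 11.5, and 45.5% to 46.4% and 46.5% to 47.4% for those of stage 26. An exact permutation test of 2 libraries against 2 cannot go below p = 0.33. The 3 rows share the 7-base stretch GGCAGTG, at bases 2 to 8 from the 5′ end of miR-449 (AGGCAGTGTAATGTTAGCTGGT) and miR-34a (TGGCAGTGTCTTAGCTGGTTGTT) and at bases 3 to 9 of miR-34b (CAGGCAGTGTAGTTAGCTGATTG). miR-449 went from 42402 ± 6685 to 388443 ± 5666 CPM, 9.16-fold in share, and rose after scaling (log2 fold change 1.22, SE 0.108, limma adjusted p = 0.000746). With the miR-427 family left out of the totals its log2 fold change was 0.62 (limma adjusted p = 0.0284, within a range of 1.15e-07 to 0.0868 over all alternatives). miR-34b went from 247.9 ± 211 to 69392 ± 2229 CPM, with a scaled log2 fold change of 6.26 (SE 0.719, limma adjusted p = 0.00167). Its stage 11.5 value rested on 12 reads in all, and the ratio of pooled reads was 306.5 in share, with an interval of 175.3 to 593.5. After scaling that ratio was 77.6 (interval 44.4 to 150.3). Without library a of stage 11.5 its log2 fold change was 7.31, and without b 5.35. miR-34a went from 1837 ± 459 to 6881 ± 884 CPM, which was higher in CPM (log2 1.89, limma adjusted p = 0.00748) but did not pass after scaling (log2 -0.06, SE 0.414, limma adjusted p = 0.908). Its scaled log2 fold change was 0.30 without library a of stage 11.5 and -0.36 without b, and passed in neither. In the list, 2 of 3 members passed the test, both over all miRNAs and adjusted over the list alone. Camera did not place the list apart from other miRNAs (adjusted p = 0.304, and adjusted p = 0.41 with an estimated correlation).

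**Figure D2:**
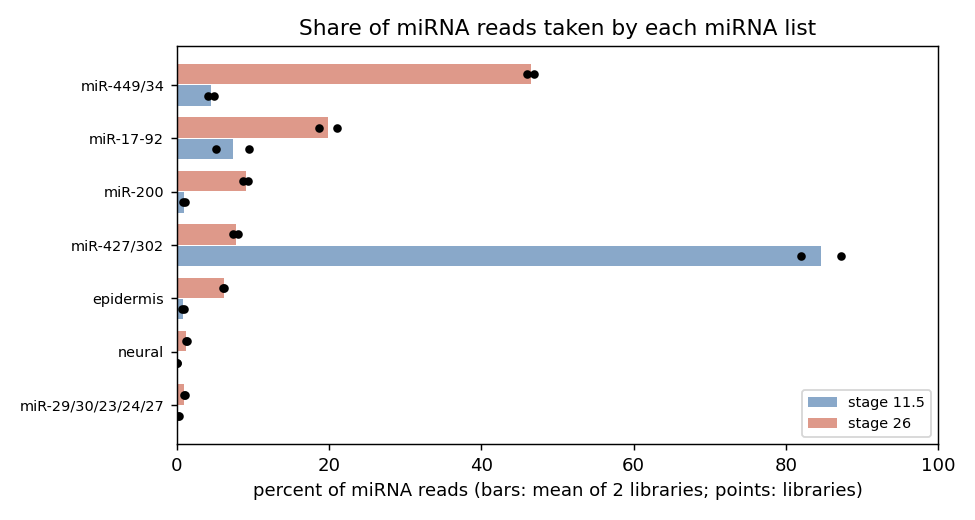
Percent of miRNA reads (horizontal axis) in the 7 lists that exceeded 0.5% at either stage. Bars are means of the 2 libraries of a stage and points are libraries. The early embryonic list around miR-427 held 84.6% at stage 11.5 and 7.74% at stage 26, while the miR-449/34 list went from 4.45% to 46.5%.

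The list of early embryonic miRNAs miR-427, miR-428, miR-302 and miR-367 went from 84.6% ± 3.73 to 7.74% ± 0.475 of reads (SD, n = 2), and from 1.59% ± 0.0837 to 0.518% ± 0.0469 with the miR-427 family left out. Nearly all of this was miR-427, at 843558 ± 38009 CPM at stage 11.5 and 72599 ± 4333 CPM at stage 26, a drop of 11.6-fold in share (scaled log2 fold change -5.52, SE 0.1001, limma adjusted p = 7.64e-06). miR-428 took 1995 ± 388 and 4793 ± 430 CPM. It was higher in CPM (log2 1.25, limma adjusted p = 0.0306) and did not pass after scaling (log2 -0.69, SE 0.356, limma adjusted p = 0.157). It fell with the miR-427 family left out of the totals (log2 -1.29, limma adjusted p = 0.0319). Without miR-20b, miR-93a, miR-93b and miR-92a it also fell (log2 -0.85, limma adjusted p = 0.0396). In 13 of 16 alternatives miR-428 did not pass, within a range of 0.0306 to 0.387 over all alternatives. Of the list's 2 tested members, 1 fell, also when adjusted over the list alone. Of the untested rows, miR-302 had 1 read in all. miR-367, named after its values were seen, had 6 and 23 reads in libraries a and b of stage 11.5 and 0 at stage 26, at least 15.1-fold lower in share. It missed the CPM limit in library a, and the filter asks for 2 libraries. With 1 library left out, the filter asked for 1 library alone. The list then had 3 tested members in 3 cases: without stage 11.5 a, without stage 26 a and without stage 26 b.

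The miR-17-92 list, known from proliferating cells, was the second largest at both stages by share of all reads, with 7.31% ± 3.11 and 19.8% ± 1.69 (SD, n = 2). With the miR-427 family left out of the totals it took 45.7% ± 8.77 and 21.3% ± 1.92, and its mean share was the largest of the lists at stage 11.5. Of the rows of this list, miR-93b lies within miR-93a and has nearly equal reads (1272 and 1267), so they are not separate evidence. None of its 12 tested members rose after scaling, 2 fell (miR-19a and miR-363-3p), and 10 did not pass, with the same counts when adjusted over the list alone. In CPM 6 were higher and none lower. The most abundant, miR-17-5p, went from 17385 ± 307 to 64476 ± 4361 CPM (scaled log2 -0.09, limma adjusted p = 0.725; CPM log2 1.89). miR-18a went from 14927 ± 2331 to 57548 ± 4087 CPM (scaled log2 -0.03, limma adjusted p = 0.908; CPM log2 1.95). The CPM changes of miR-17-5p and miR-18a lay close to the 1.98 (log2) by which scaling moved the stages. TMM gives most weight to abundant rows, so rows like these can help set the scale. Their small scaled values are therefore no independent evidence of unchanged levels. With the miR-427 family left out of the totals, their log2 fold changes were -0.70 and -0.63. miR-20b was at 12970 ± 12914 and 18333 ± 5529 CPM, and its stage 11.5 libraries differed from each other 5.76-fold, more than the stages did. Its scaled log2 fold change was -1.02 (limma adjusted p = 0.387), and -2.17 without library a of stage 11.5 and 0.19 without b. miR-363-3p, at 731 ± 35.8 and 601 ± 95.8 CPM, fell after scaling (log2 -2.10, SE 0.256, limma adjusted p = 0.00184) and did not pass in CPM (log2 -0.27, limma adjusted p = 0.375). Camera gave adjusted p = 0.169 for the list, adjusted p = 0.41 with an estimated correlation, and 0.0418 without library a of stage 11.5, within a range of 0.0418 to 0.508 over all alternatives.

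Epithelial miRNAs took larger shares at stage 26, as did most tested miRNAs. The miR-200 family, a marker of epithelia, went from 0.914% ± 0.126 to 9.04% ± 0.5005 of reads (SD, n = 2), and from 5.92% ± 0.633 to 9.74% ± 0.494 with the miR-427 family left out of the totals. All 3 members were higher in CPM. After scaling 1 of the 3 rose, also when adjusted over the list alone. This was miR-429, from 5609 ± 1881 to 62846 ± 1929 CPM (log2 1.54, SE 0.314, limma adjusted p = 0.0132). miR-200a had a scaled log2 fold change of 0.98 (SE 0.353, limma adjusted p = 0.0696) and miR-200b of 1.04 (SE 0.531, limma adjusted p = 0.157). miR-200a passed in 6 of 16 alternatives, among them the omission of library a or b of stage 11.5 (limma adjusted p = 0.0258 and 0.0366), relative log expression factors (0.0349), a filter at a mean of 100 CPM (0.0366) and the fit without a trend (0.0343), within a range of 0.000773 to 0.426. Without library a of stage 11.5, miR-200b passed (log2 1.74, limma adjusted p = 0.0362), and without b it did not (log2 0.42, limma adjusted p = 0.246), within a range of 0.00164 to 0.642. Camera gave adjusted p = 0.31 for the list, and adjusted p = 0.41 with an estimated correlation. In the epidermis list, miR-203, known from stratified skin, was the 1 tested member. The list took 0.802% ± 0.144 and 6.14% ± 0.1496 of reads (SD, n = 2), and 5.40% ± 2.23 and 6.62% ± 0.1304 with the miR-427 family left out of the totals. In the latter shares the stage 11.5 libraries spread more than the stages differed. miR-203 went from 8024 ± 1441 to 61333 ± 1570 CPM (scaled log2 0.96, SE 0.290, limma adjusted p = 0.0415). Its call was also lost with no filter (limma adjusted p = 0.0603) and with the miR-427 family out of the totals (limma adjusted p = 0.426). It was lost again without miR-20b, miR-93a, miR-93b and miR-92a (0.0758) and without miR-93b and miR-29c (0.0706), within a range of 0.000256 to 0.426 over all alternatives.

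The let-7 family, whose members are near-identical and can share reads, went from 0.449% ± 0.0820 to 0.119% ± 0.00322 of reads (SD, n = 2), and from 3.03% ± 1.26 to 0.129% ± 0.00407 with the miR-427 family left out of the totals. Its 4 tested members split into 3 that fell and 1 that rose, also when adjusted over the list alone and in CPM. let-7i stood at 1473 ± 149 CPM at stage 11.5 and 0 in both stage 26 libraries, at least 43.6-fold lower in share and at least 172-fold after scaling (limma adjusted p = 6.47e-05). let-7b fell from 1942 ± 560 to 281 ± 25.4 CPM (scaled log2 -4.33, SE 0.348, limma adjusted p = 0.000624) and let-7f from 1078 ± 409 to 352 ± 75.9 CPM (scaled log2 -3.23, SE 0.400, limma adjusted p = 0.00188). let-7a was at 0 in both stage 11.5 libraries and at 405 and 334 CPM at stage 26. Camera gave adjusted p = 0.169, adjusted p = 0.41 with an estimated correlation, and 0.0134 in CPM, within a range of 0.0134 to 0.481 over all alternatives. In the list of the miR-29, 30, 23, 24 and 27 families, common in differentiated tissues, 4 of 5 tested members rose and none fell, also when adjusted over the list alone. Among the 4 are miR-23a and miR-23b, whose sequences are near-identical. They had 28 and 28 reads in library a of stage 26 and 24 and 20 in library b, so they may not be separate evidence. The others, miR-30a-5p and miR-30e, are also near-identical to each other and to miR-30d. As the mismatches allowed are not given, these may not be separate evidence either. The share of reads of this list went from 0.166% ± 0.110 to 0.988% ± 0.0311 (SD, n = 2), but was 1.004% ± 0.457 and 1.07% ± 0.0286 with the miR-427 family left out of the totals. Camera gave adjusted p = 0.207, and adjusted p = 0.41 with an estimated correlation. miR-30a-5p rose from 1 read at stage 11.5 to 1289 ± 439 CPM (limma adjusted p = 0.00399), a ratio of pooled reads of 69.4 in share with an interval of 12.2 to 2763. After scaling that ratio was 17.6 (interval 3.09 to 699.8). Its scaled log2 fold change was 3.18, and 2.75 without library a of stage 11.5 and 4.06 without b. With pseudocounts of 10 and 200 CPM it was 4.57 and 1.87. miR-23a, also with 1 read at stage 11.5, reached 585 ± 16.99 CPM (ratio 31.1 in share, interval 5.34 to 1251, limma adjusted p = 0.0300). After scaling that ratio was 7.875 (interval 1.352 to 317). Its scaled log2 fold change was 2.03, and 3.10 without library a of stage 11.5 and 1.36 without b. With pseudocounts of 10 and 200 CPM it was 3.25 and 1.03. Its call was also lost with no filter (limma adjusted p = 0.0603), a pseudocount of 10 CPM (0.107), the miR-427 family out of the totals (0.0838), and both omissions of rows (0.0813 and 0.0618), within a range of 0.00026 to 0.312 over all alternatives. miR-30d did not pass after scaling (log2 0.25, SE 0.570, limma adjusted p = 0.725). Its sign turned with the stage 11.5 library left out, at log2 -0.40 without a (limma adjusted p = 0.117) and 0.96 without b (limma adjusted p = 0.0376), within a range of 0.0144 to 0.919 over all alternatives. miR-10c, encoded in a Hox cluster, was at 0 at stage 11.5 and 1010 ± 192.2 CPM at stage 26, at least 17.9-fold higher in share and at least 4.53-fold after scaling (limma adjusted p = 0.00033).

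Lists of other cell types each took at most 1.20% of reads at either stage. Of the neural list, miR-218 rose from 1 read to 10825 ± 1104 CPM (limma adjusted p = 0.000849), with a ratio of pooled reads of 572 in share and an interval of 102 to 22620. After scaling that ratio was 144.9 (interval 25.95 to 5731). Its scaled log2 fold change was 6.02, and 7.14 without library a of stage 11.5 and 5.39 without b. With pseudocounts of 10 and 200 CPM it was 7.41 and 4.54. miR-7 went from 391 ± 134 to 1203 ± 47.2 CPM and did not pass after scaling (log2 -0.30, limma adjusted p = 0.504; CPM log2 1.54, limma adjusted p = 0.00453). Its sign also turned with the stage 11.5 library left out, at log2 0.14 without a (limma adjusted p = 0.419) and -0.68 without b (limma adjusted p = 0.0493), within a range of 0.00453 to 0.781 over all alternatives. The neural list as a whole took 0.0413% ± 0.0165 and 1.20% ± 0.106 of reads (SD, n = 2), and 0.285% ± 0.175 and 1.30% ± 0.108 with the miR-427 family left out of the totals. The muscle list took 0.0720% ± 0.00419 and 0.151% ± 0.0121 (0.478% ± 0.143 and 0.163% ± 0.0123 with the miR-427 family left out of the totals), with miR-1b lower after scaling (log2 -1.06, SE 0.289, limma adjusted p = 0.0328) and higher in CPM (log2 0.82, limma adjusted p = 0.0404). Its scaled call was also lost with no filter (limma adjusted p = 0.0580, within a range of 0.0166 to 0.21 over all alternatives). The endoderm list took 0.0716% ± 0.0547 and 0.291% ± 0.0166 (0.515% ± 0.475 and 0.314% ± 0.0193 with the miR-427 family left out, where the stage 11.5 libraries spread more than the stages differed). Within it miR-215 was at 0 at stage 11.5 and 1396 ± 255 CPM at stage 26 (at least 24.7-fold higher in share and 6.26-fold after scaling, limma adjusted p = 0.000242), and miR-375 did not pass (scaled log2 -0.66, limma adjusted p = 0.454; CPM log2 1.21). Its sign turned with the stage 11.5 library left out, at log2 0.28 without a (limma adjusted p = 0.571) and -1.56 without b (limma adjusted p = 0.0561), within a range of 0.0561 to 0.826 over all alternatives. The blood and vessel list took 0.115% ± 0.0190 and 0.0330% ± 0.00741 (0.741% ± 0.0590 and 0.0355% ± 0.00783 with the miR-427 family left out), with miR-126, known from endothelium, falling from 967 ± 307 to 150.1 ± 91.6 CPM (scaled log2 -3.99, SE 0.374, limma adjusted p = 0.000849). The sensory list was at 0 at stage 11.5, which allows up to 56.5 CPM over both libraries, and took 0.0739% ± 0.01002 at stage 26. Its miR-182 was at 649 ± 107 CPM there, at least 11.5-fold higher in share and 2.91-fold after scaling (limma adjusted p = 0.000383). The mesenchyme list held 0 reads at stage 11.5 and 0.0398% ± 0.0191 at stage 26, the list of miR-99, miR-100 and miR-125 0.0385% ± 0.0107 and 0.0246% ± 0.00441 (0.245% ± 0.00907 and 0.0265% ± 0.00488 with the miR-427 family left out), and the miR-15/16 list 0.00164% ± 0.00233 and 0.0102% ± 0.00241 (0.00897% ± 0.0127 and 0.0110% ± 0.00255 with the miR-427 family left out, the former from 1 read), none with a tested member. The Hox cluster list held 0 reads at stage 11.5 and 0.139% ± 0.0302 at stage 26.

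Among the largest changes outside the lists, miR-301 was at 0 at stage 11.5 and 1631 ± 226 CPM at stage 26, at least 28.9-fold higher in share and 7.31-fold after scaling (limma adjusted p = 0.000181). miR-130b rose from 610.0 ± 114 to 20500.2 ± 1638 CPM, 33.6-fold in share (scaled log2 3.05, SE 0.360, limma adjusted p = 0.00172). miR-155, known from immune cells, stood at 1798 ± 264 CPM at stage 11.5 and at 1 read at stage 26. Its ratio of pooled reads was 157 in share with an interval of 27.5 to 6275 (limma adjusted p = 0.000156). After scaling that ratio was 620.7 (interval 108.7 to 24770). miR-222 took 302.4 ± 9.06 and 236.7 ± 2.97 CPM, fell after scaling (log2 -1.94, SE 0.204, limma adjusted p = 0.00127) and did not pass in CPM (limma adjusted p = 0.215). The 46 untested miRNAs had means of at most 255.3 CPM over the 4 libraries, and 31 of them were at 0 at stage 11.5. With no filter, 48 of the 98 miRNAs passed, and 25 of the 31 calls were kept.

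**Figure D3:**
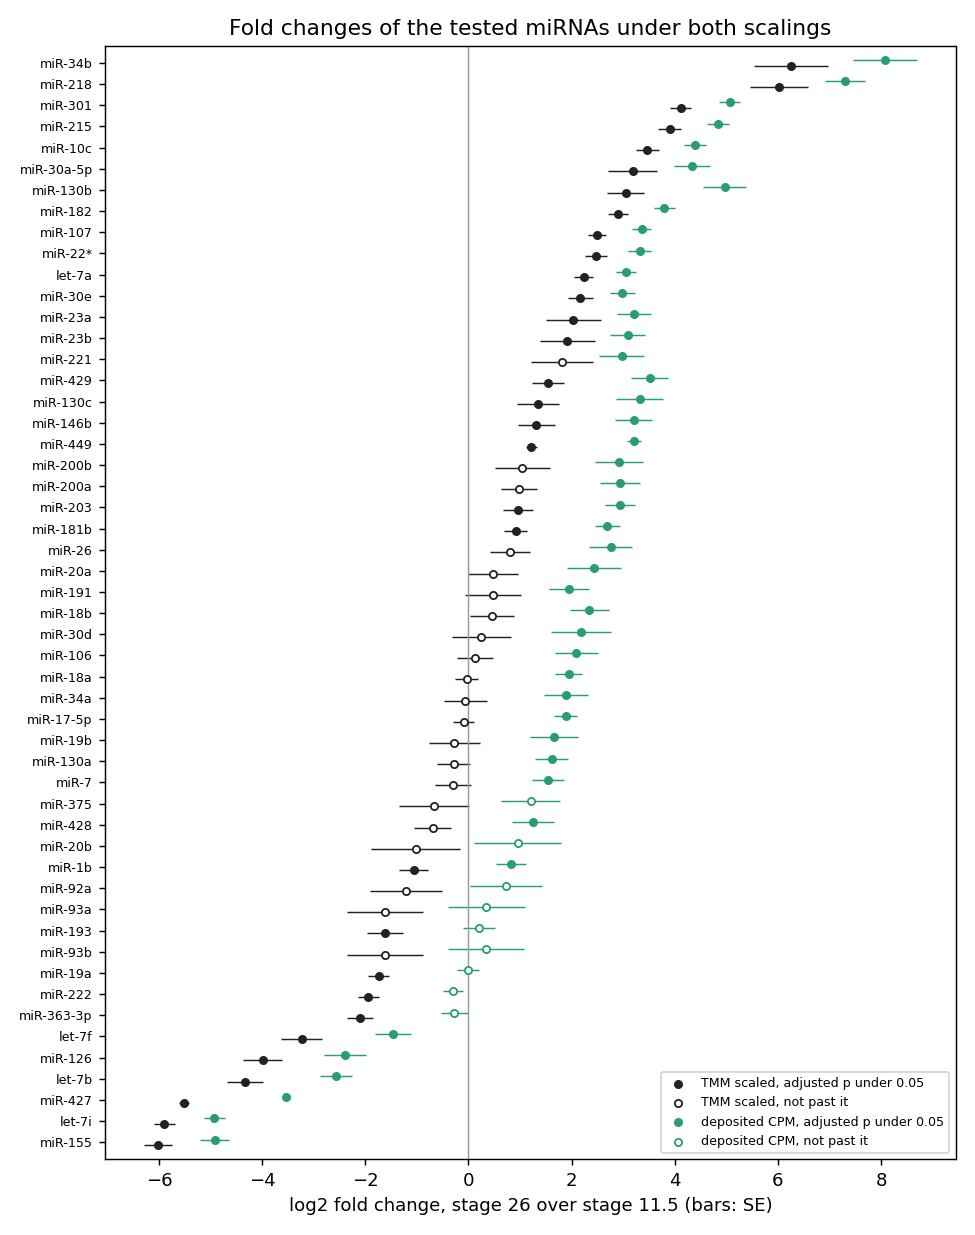
Log2 fold change (stage 26 over stage 11.5, horizontal axis) of the 52 tested miRNAs, TMM scaled (black) and in the deposited CPM (green), with SE bars and filled points where adjusted p was under 0.05. The green points lie to the right of the black ones, by 1.86 at the median, and 6 are called lower in CPM against 11 after scaling.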

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

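The comparison of the stages was recomputed under 17 alternatives, of which the pseudocounts, the fit without a trend, the voom weights and the omissions of rows were chosen after seeing the data. In 14 of these the count of changed miRNAs stayed within 1.5 times the 31 reported. With no filter it was 48 of 98 tested, and 44 against 29 for changes of at least 2-fold. With 1 library left out it ranged from 11 (without stage 26 a) to 41 (without stage 11.5 b), and from 11 to 37 at least 2-fold. The lone library is then assumed to vary like the other stage. Without stage 26 a or b, the spread comes from the stage 11.5 libraries alone. Rows at 0 in both of these then have no spread of their own. These omissions therefore cannot test such rows, among them miR-301, miR-215, miR-10c and miR-182. Why other calls were lost was not tested. No list passed camera in the reported fit, and 1 did in the deposited CPM (let-7, camera adjusted p = 0.0134). With 1 library left out, the looser filter also changed which miRNAs and lists were tested. The early embryonic list could then be tested without stage 11.5 a, stage 26 a or stage 26 b, so the number of lists passing is not directly comparable. With the miR-427 family left out of the totals, the miR-449/34 list took 28.8% and 50.1% of reads at stages 11.5 and 26, which follows from the smaller totals. The early embryonic list took 1.59% and 0.518%, because miR-427 itself was then left out of that list as well. Of 28 other list shares, 16 moved by more than their SD under this change.

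The deposited CPM gave calls of the opposite sign for miR-34a (log2 1.89), miR-17-5p (1.89), miR-18a (1.95), miR-428 (1.25), miR-1b (0.82) and miR-7 (1.54), all below 0 after scaling, where miR-1b alone passed. Scaling alone differs there, by 1.98 on the log2 scale. Over the 31 named miRNAs and the 16 alternatives that keep rows apart, 435 fits gave the reported call, 39 lost the call and 13 gained it. Of 21 named calls, 7 were kept in each of these 16: miR-301, miR-215, miR-10c, miR-182, miR-155, let-7i and miR-427. Of these, miR-301, miR-215, miR-10c and miR-182 were at 0 in both stage 11.5 libraries, and let-7i in both stage 26 libraries. In fits on log2 CPM the pseudocount sets both such libraries to the same value, with no spread in that stage. Being kept is therefore no sign of reproducible levels in that stage for these rows. With a library of the other stage left out, these rows have no spread of their own at all. Those omissions cannot test them, so these rows are not shown to be more robust than miR-449 or miR-34b. With the replicate letter as a block, 29 miRNAs were called and 28 of the reported calls were kept, and miR-1b was the named call lost (limma adjusted p = 0.116, within a range of 0.0166 to 0.21). Deviations of libraries with the same letter correlated with r = -0.26 over 52 miRNAs, and the letters are not stated to pair libraries. The planned DESeq2 alternative was not run, because the deposited values are CPM and the recovered reads have no independent check. At 22668 to 46892 reads per library, a miRNA at 0 in both stage 11.5 libraries was bounded only at 56.5 CPM.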

Other observations

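Outside the lists, 14 miRNAs were tested, of which 7 rose, 3 fell and 4 did not pass. The 4 rows of the miR-130 and miR-301 families together went from 0.447% ± 0.140 to 5.51% ± 0.387 of reads (SD, n = 2), and from 2.83% ± 0.204 to 5.94% ± 0.390 with the miR-427 family left out of the totals. After scaling miR-130b, miR-130c and miR-301 rose, and miR-130a did not pass (log2 -0.28, limma adjusted p = 0.495). The stretch AAGTGC, at bases 3 to 8 of miR-427, starts at or before base 4 in 9 rows, among them miR-17-5p, miR-20b, miR-93a and miR-428. These 9 rows took 89.8% ± 1.02 of reads at stage 11.5 and 20.6% ± 2.37 at stage 26. Without miR-427 they took 5.44% ± 2.78 and 13.3% ± 1.94 of all reads, but 33.6% ± 9.63 and 14.4% ± 2.15 of the reads other than miR-427, so the direction turns with the total used. These groupings were chosen after their values were seen.

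All tests below were chosen after the results were seen, except the test of GC content. Most miRNAs took a larger share of reads at stage 26, with a median log2 change of 2.35 over the 51 tested miRNAs other than miR-427. With the miR-427 family left out of the totals that median was -0.121. This omission shifts all other rows alike, by an amount set by the shares of miR-427, so it is no independent test. The loss of miR-427 reads is a candidate explanation for the general rise in share. A rise of other miRNAs per explant cannot be told apart from it, because the table holds 0 rows that are not miRNAs and could serve as an internal standard.

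The rows of miR-20b, miR-93a, miR-93b and miR-92a differed between the libraries of a stage: at stage 11.5 library b exceeded a by 5.76, 3.62, 3.58 and 3.43-fold, and at stage 26 library a exceeded b by 1.54, 2.08, 2.09 and 1.89-fold. Counting noise is argued against by a chi-square per degree of freedom of 7.1 at stage 26 and 20.6 at stage 11.5, and GC content by a median shift of -0.0324 (interval -0.1 to 0.255) at stage 26 in the 11 other miRNAs of at least 47.8% GC. At stage 11.5 the median log2 shift of those 11 miRNAs (b minus a) was -0.646 (interval -1.54 to 0). Its sign is opposite to the higher values of miR-20b, miR-93a, miR-93b and miR-92a in b. Reads passed among the miR-17, miR-18, miR-20, miR-93 and miR-106 rows are argued against at stage 11.5 by the log2 ratio of their sum. It was 0.92 (b over a, interval 0.817 to 1.02). The sum leaves out miR-427, which shares the stretch AAGTGC with miR-20b and miR-93a. As miR-427 took 87.0% of stage 11.5 reads in library a and 81.7% in b, reads passed between it and these rows are not covered. At stage 26 the same sum (a over b) gave 0.16 (interval 0.116 to 0.204), which decides nothing. The other rows gave 0.0046 (interval -0.0441 to 0.0532) where passed reads needed -0.14. That interval covers counting error only, and single rows among them differed by about as much as this gap. In libraries a and b, miR-17-5p took 6.76% and 6.14% of reads, and miR-18a 5.47% and 6.04%. The other rows therefore cannot decide the question at stage 26, and neither stage's test covers miR-92a. Libraries prepared in crossed pairs stay open (same-letter r = 0.24 without these rows, interval -0.0476 to 0.49), as does, untested, a difference between explants, since the source name of each library b gives a slightly later stage although 1 pool per stage is described.

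The sequence of miR-93b lies within that of miR-93a, and that of miR-29c within that of miR-29a. Their rows had 1267 and 1272 reads, and 19 and 19 reads, with a largest difference of 3 in a library. The larger chi-square per library was 0.0041, far below that of independent counts, which is consistent with reads counted in both rows. No biological explanation was tested for this pattern.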
